A study of Mus musculus with 6 samples.

How the data were processed

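The series holds 6 RNA sequencing libraries of CD4+ T cells sorted from mouse liver, 3 from mice given ConA and vehicle and 3 from mice given ConA and simvastatin. Per the labels' protocols the cells were sorted by flow cytometry, total RNA was taken and libraries were made with standard Illumina reagents. Per the submitters' processing notes, HISAT2 2.1.0 and the mouse genome build GRCm38 were used. The counting tool, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. The authors deposited 1 table of raw counts per gene, whole numbers that were not normalized, with a column per sample and gene symbols as row names. Each column carries the title of 1 sample, which gave its group and replicate number, and 0 columns were left unused. All 23505 row names were found in the RefSeq gene table of GRCm38, once the numbered suffix that marks further copies of a symbol was removed, and gene coordinates are from that table. Rows with such a suffix numbered 1618 and took between 0.295% and 0.351% of the counts of a library; 0 of the 57 called genes had such a copy.

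The labels do not say that the samples of a group came from separate animals or pools, so p-values measure the spread between these samples, which may be technical. The labels name no batch. No pair of libraries within a group agreed within sampling noise: the chi-square statistic of their counts was 147 to 305 times its degrees of freedom. The total count per library was 21825105, 18360352 and 25031862 in ConA replicates 1 to 3 and 20441213, 17549429 and 20025645 in ConA+SIM replicates 1 to 3. A gene with 0 counts could hold up to 3 counts at 95% confidence, 0.118 to 0.175 CPM, which covers counting error only. The common biological coefficient of variation was 1.12, and ConA+SIM replicate 2 had 18.4% of tested genes at 0 counts against 2.76% to 9.98% in the other libraries.

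From the deposited counts, genes were kept with the filterByExpr function of edgeR 4.0.16, scaled with TMM factors and tested with its quasi-likelihood F test with robust settings in R 4.3.3, ConA+SIM over ConA, without covariates. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. CPM values are counts relative to the TMM-scaled library total, as given by the cpm function of edgeR. Gene lists were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, each list against all other tested genes, with adjustment over the lists together. There were 24 gene lists (SREBP2 targets, LXR targets, small GTPases and prenyl transferases, calcium and NFAT, T cell receptor signalling, activation response, Th1, Th2, Th17, regulatory, follicular helper, naive and central memory, inhibitory receptors, cell cycle, apoptosis, type I interferon, interferon gamma, NF-kappaB, glycolysis, oxidative phosphorylation, ribosomal proteins, unfolded protein response, heat shock, chemokine receptors and adhesion) and 13 marker lists of other cell types and sex chromosome genes. Lists with fewer than 5 tested members were not tested, which left 32. A list's direction in the test can differ from that of its median, since camera compares moderated statistics.

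The gene lists, tests and rule for naming genes were fixed before the data were examined. Genes named are the 10 with the largest rise and the 10 with the largest fall among those past the threshold, with at least 10 CPM in the higher group and replicates that do not overlap, up to 4 members of each list with the smallest adjusted p under 0.05, and 17 genes named whatever their p. Where fewer than 5 passed in a direction, the 5 with the smallest p were named as not passing. Some genes that this rule names are not reported here. Other list members given in the text were chosen after their values were seen.

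Alternatives fixed in advance were RLE scaling, no filter on low counts, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, an added log2 fold change limit of 1, the replicate number as a block, leaving out each library, camera with an estimated correlation, fry, hepatocyte, erythroid and immunoglobulin genes left out, and a hepatocyte score as covariate. Alternatives added after seeing the data were offsets that remove each library's trend with transcript length, or with length and GC content, summing the copy rows, and leaving out ribosomal protein genes. Transcript length, coding length and GC content came from GENCODE release M21 on GRCm38, with 1 transcript per gene, and 95.5% of tested genes had a length. The procedure was tested on simulated data drawn from the real means of 10509 genes for the comparison of ConA+SIM with ConA. It called 13% of genes changed 4-fold and 0% of genes changed 2-fold, and 27.7% of the 4-fold changed genes in the more abundant 50% of genes; 4 unchanged genes were called. DESeq2 gave no p for 1671 genes with counts. In simulated data the camera test gave p = 5.65e-07 for a moved list and 0.584 for an unmoved list, and the length correction took a simulated correlation with length from -0.71 to -0.016. The simulated genes were drawn independently, whereas the real ribosomal protein list had an estimated correlation between genes of 0.27. The simulation therefore cannot show how camera with its preset correlation treats lists of correlated genes.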

Results

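Gene expression was measured by RNA sequencing in CD4+ T cells sorted from the livers of mice injected with concanavalin A (ConA), a plant lectin that activates T cells and causes an immune-mediated hepatitis. The ConA group received the vehicle, phosphate-buffered saline, by gavage, and the ConA+SIM group received simvastatin, a cholesterol-lowering statin, at 30 mg/kg. Both groups were gavaged daily for 5 days before ConA, again 1 h before it and once more 24 h after it. The sort kept CD3-positive, CD4-positive cells that lacked CD8 and NK1.1, an antigen of NK cells. Each group held 3 samples, and each sample gave 1 library. Total counts ran from 17549429 in ConA+SIM replicate 2 to 25031862 in ConA replicate 3. Of 23505 gene rows, 10278 had no count in any library and 10509 had enough counts to be tested.

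The comparison of ConA+SIM with ConA asks how simvastatin altered liver CD4+ T cells in this hepatitis, and the series title names T cell activation, calcium and NFATC3. In ConA+SIM, 57 genes rose and 0 fell (edgeR quasi-likelihood test, adjusted p under 0.05). Genes encoding cytosolic ribosomal proteins and their close paralogs made up 38 of the 57, out of 84 such genes tested. Among them, Rpl26, a protein of the large ribosomal subunit (chromosome 11, 68901566 to 68904534, GRCm38), rose from 1184 ± 211 to 3549 ± 511 CPM (counts relative to the scaled library total; SD, n = 3 per group), a log2 fold change of 1.58 ± 0.18 (SE, adjusted p = 0.0301). Rps27a, which encodes a fusion of ubiquitin and a ribosomal protein, rose by 1.70 ± 0.24, Rpl34 by 1.70 ± 0.23, Rpl22l1 by 1.67 ± 0.23 and Rps27l by 1.75 ± 0.26. The remaining 19 genes included Cd69, an early activation and tissue-retention marker of T cells, which rose from 387 ± 106 to 981 ± 51.0 CPM (log2 fold change 1.34 ± 0.22, adjusted p = 0.0397; chromosome 6, 129267324 to 129275375).

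The largest rise among the 57 was that of Hbb-bs, an adult beta-globin gene (chromosome 7, 103826523 to 103827928), from 40.8 ± 7.25 to 171 ± 55.9 CPM (log2 fold change 2.07 ± 0.36, adjusted p = 0.0485). Stk26, a serine/threonine kinase gene on chromosome X, rose by 1.91 ± 0.32 on the log2 scale, from 73.7 ± 27.1 to 277 ± 28.7 CPM. The mitochondrial ribosome gene Mrpl33 rose by 1.73 ± 0.30 and the cytochrome c oxidase subunit gene Cox6c by 1.56 ± 0.25. Pcna, the DNA polymerase clamp, rose by 1.07 ± 0.18, the cytosolic chaperone gene Hsp90aa1 by 1.27 ± 0.15 and the interferon-inducible gene Ifi27l2a by 1.38 ± 0.20. The smallest of the 57 rises was 0.81, and in all 57 genes the 3 ConA+SIM values lay above the 3 ConA values. Such separation in either direction was seen in 17.8% of tested genes, where chance gives 10%.

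No gene fell by the edgeR test. The lowest p-values among genes with lower values in ConA+SIM belonged to Prpf8, a core spliceosome component, at 463 ± 52.3 CPM in ConA and 193 ± 43.1 in ConA+SIM (log2 fold change -1.26 ± 0.24, adjusted p = 0.0652), and to the non-muscle myosin gene Myh9 (-0.92 ± 0.18, adjusted p = 0.0743). Srrm1, a splicing factor gene, had a log2 fold change of -1.25 ± 0.26, the focal adhesion kinase relative Ptk2b one of -1.31 ± 0.29 and the talin gene Tln1 one of -1.02 ± 0.23, each also short of the threshold. The transcripts of these genes were 3797 to 8393 nt long. After transcript length correction Prpf8 stood at -0.86 and Myh9 at -0.57, and with GC correction as well at -0.58 and -0.049. Over 20 alternatives Srrm1 ran from -1.49 to -0.90, Ptk2b from -1.60 to -0.75 and Tln1 from -1.36 to -0.11. At an unadjusted p under 0.05 there were 930 genes, 558 higher and 372 lower. DESeq2 called 347 genes higher and 193 lower, limma-voom 108 and 7, and voom with sample quality weights 110 and 4; all 57 edgeR calls were also called by each of these.

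The 57 calls depended on having all 6 libraries. Leaving out ConA replicate 1, 2 or 3 or ConA+SIM replicate 1 or 2 gave 0 calls, and leaving out ConA+SIM replicate 3 gave 3, whereas all 57 genes kept their direction each time. The call of Cd69 ended in each of these 6 fits, with log2 fold changes from 1.22 to 1.58. Over all 20 alternatives it passed in 9, with log2 fold changes from 0.71 to 1.58. The value was 1.14 after transcript length correction (adjusted p = 0.421) and 0.71, the lowest, after length and GC correction (adjusted p = 0.944). With ribosomal protein genes left out it was 1.34 (adjusted p = 0.127), and 0 of the 19 calls outside that family passed.

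**Figure D1:**
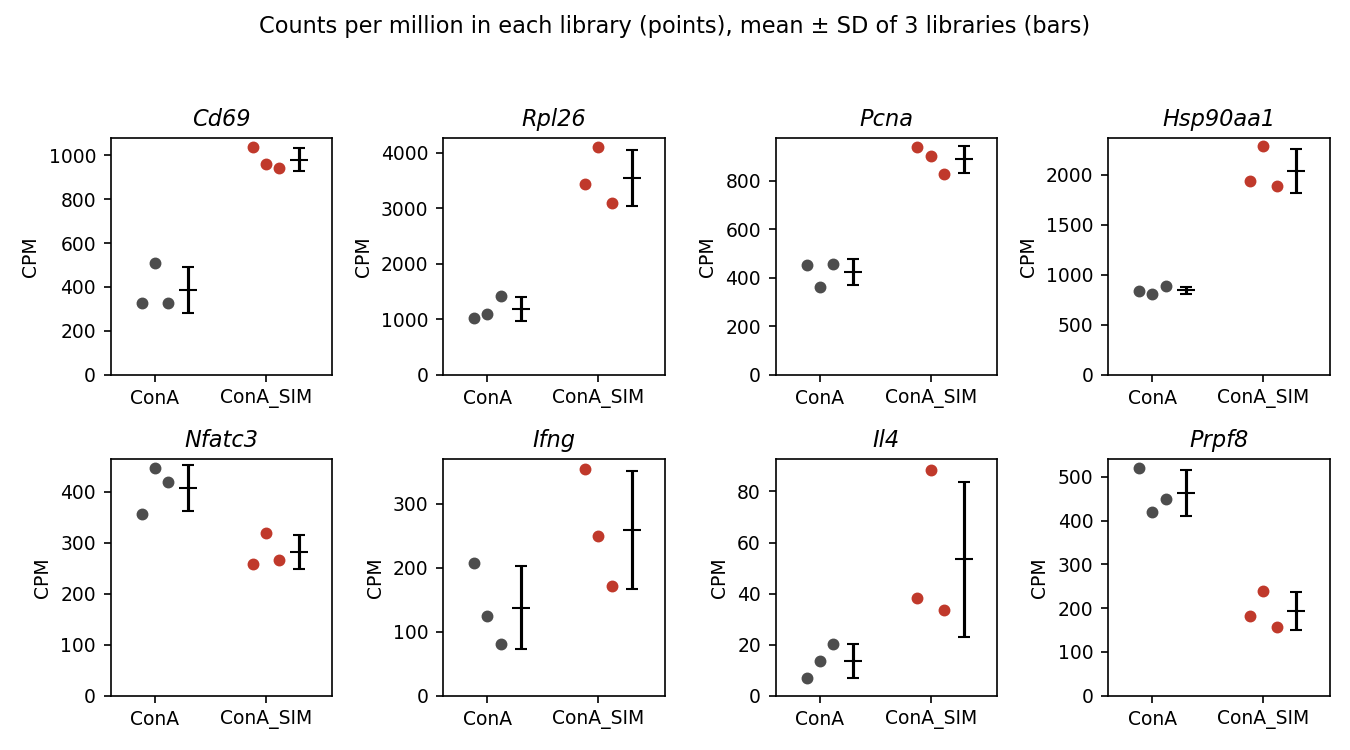
CPM (vertical axis, starting at 0) of 8 genes in each of the 3 ConA and 3 ConA+SIM libraries (points; labelled ConA_SIM on the axis), with the mean ± SD of each group beside them. Cd69, Rpl26, Pcna and Hsp90aa1 passed the edgeR test, whereas Nfatc3, Ifng, Il4 and Prpf8 did not; Nfatc3 ran from 357 to 447 CPM in ConA and from 258 to 320 CPM in ConA+SIM.

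The calcium and calcineurin-NFAT list held 32 tested genes, of which 9 had higher and 23 lower values in ConA+SIM, and 0 passed the test over all genes. Nfatc3, the transcription factor named by the series title (chromosome 8, 106058818 to 106130537), stood at 408 ± 45.8 CPM in ConA and 281 ± 33.4 in ConA+SIM, a log2 fold change of -0.54 ± 0.21 that did not pass (adjusted p = 0.472), although the replicates of the groups did not overlap. Nfatc1 had a log2 fold change of -0.77 ± 0.33 (adjusted p = 0.552) and Nfatc2 one of -0.76 ± 1.46, with 0 counts in ConA+SIM replicate 2. Calm2, 1 of the calmodulin genes, was the sole member to pass when adjusted over the list alone (1.11 ± 0.21, adjusted p = 0.0168). The median log2 fold change of the list was -0.36, and its test gave an adjusted p = 0.141 (camera). After correction for transcript length the log2 fold change of Nfatc3, whose transcript is 5984 nt long, was -0.20.

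Of 33 genes that respond to T cell activation, Cd69 rose, 0 fell and 32 did not pass, over all genes and adjusted over the list alone. The immediate early gene Egr1 stood at 358 ± 70.4 CPM in ConA and 191 ± 33.3 in ConA+SIM, and Il2ra, the high-affinity interleukin-2 receptor chain, at 78.9 ± 12.0 and 62.4 ± 12.3 CPM. The list had a median of -0.13 (adjusted p = 0.561); it was called lower without ConA+SIM replicate 2 (adjusted p = 0.0169) and with quality weights (adjusted p = 0.0485). Among 30 T cell receptor signalling genes, 0 passed over all genes and 4 adjusted over the list alone. The receptor chain genes Cd247 (1.14 ± 0.22) and Cd3d (0.77 ± 0.22) were higher, and the inhibitory signalling genes Dgkz (-0.84 ± 0.21) and Ptpn6 (-1.22 ± 0.34) lower. The median of that list was -0.13 (adjusted p = 0.819). Cd4 stood at 599 ± 148 CPM in ConA and 491 ± 63.3 in ConA+SIM (log2 fold change -0.29 ± 0.22, adjusted p = 0.94).

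The Th1 and effector cytokine list was higher in ConA+SIM as a set, with a median of 0.47 over 25 tested genes (camera adjusted p = 0.00378), although 0 of its genes passed, also when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.407 with an estimated correlation) and after transcript length correction (median 0.28, adjusted p = 0.2; 0.23 and adjusted p = 0.603 with GC correction as well). Its values included Gzma, the granzyme A gene, at 110 ± 72.4 and 306 ± 25.6 CPM, the chemokine gene Ccl5 at 157 ± 47.0 and 285 ± 77.7 CPM, and Ifng at 137 ± 64.9 and 258 ± 91.8 CPM (log2 fold change 0.91 ± 0.40, adjusted p = 0.553). Il4, the main Th2 cytokine, stood at 13.5 ± 6.72 and 53.4 ± 30.4 CPM (1.99 ± 0.75, adjusted p = 0.443), whereas the Th2 list had a median of -0.18 (adjusted p = 0.819). The Th17 list had a median of 0.016 (adjusted p = 0.881), with Il17a at 23.7 ± 17.5 and 24.6 ± 12.4 CPM. Foxp3, the regulatory T cell factor, stood at 50.6 ± 45.0 and 29.9 ± 12.2 CPM with 0 counts in ConA replicate 2, and the regulatory T cell list had a median of 0.11 (adjusted p = 0.574). Tnf was split over 4 rows and Il2 over 3, and reads shared between such rows may have been dropped before deposit. The plain Tnf row was empty, whereas the row Tnf_2 held from 33 to 72 counts per library and was tested without passing (log2 fold change 0.10 ± 1.90, adjusted p = 0.999). The Il2 rows held at most 7 counts in a library and could not be tested.

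The follicular helper list had a median of 0.47, a mean of -0.017 and a test direction of higher (adjusted p = 0.141). The naive and central memory list had a median of -0.24 (adjusted p = 0.145; 0.00281 without ConA replicate 1 and 0.0485 with quality weights), with Klf2, a factor of T cell quiescence, at 495 ± 103 and 389 ± 36.1 CPM. The inhibitory receptor list had a median of -0.31 (adjusted p = 0.918) and the chemokine receptor and adhesion list one of -0.022 (adjusted p = 0.674). In these 4 lists 0 genes passed over all genes or adjusted over the list alone.

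Of 38 cytosolic ribosomal protein genes on the fixed list, 15 rose, 0 fell and 23 did not pass, and 23 rose when adjusted over the list alone. The list median was 0.69 (camera adjusted p = 2.71e-28), and the call was lost with an estimated correlation (adjusted p = 0.407 with an estimated correlation). After transcript length correction the list was still called by camera, with a median of 0.28 (adjusted p = 1.9e-04), as with GC correction as well (0.26, adjusted p = 1.96e-05). Examples were Rpl7 (1.22 ± 0.17), Rps23 (1.15 ± 0.16), Rps19 (1.08 ± 0.15) and Rps24 (1.06 ± 0.14), all at an adjusted p of 0.0301. Ribosomal protein genes have many processed pseudogenes, and how reads matching several places were counted is not given in the sources used here, so their levels are uncertain. Oxidative phosphorylation genes were higher as a set, with a median of 0.45 over 33 genes (adjusted p = 5.66e-04; 0.407 as the adjusted p with an estimated correlation; 0.76 after transcript length correction, with a median of 0.072; 0.876 with GC correction as well, with a median of -0.0014). Cox6c rose, and 4 genes rose adjusted over the list alone, Cox6c, Cox7c (1.38 ± 0.25), Uqcrq (2.25 ± 0.54) and Ndufa4 (1.16 ± 0.31), all small subunits of the respiratory chain.

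The cholesterol synthesis and uptake list, made of targets of the sterol-sensing factor SREBP2, had a median of -0.29 over 24 genes (adjusted p = 0.697), with 0 genes passing, also when adjusted over the list alone. The LXR target and cholesterol efflux list had a median of -0.45 (adjusted p = 0.141; 0.0485 with quality weights), with Apoe at 246 ± 2.01 and 144 ± 15.2 CPM and 0 genes passing. Of 24 small GTPase and prenyl transferase genes, 0 passed over all genes and Rap1a rose adjusted over the list alone (1.04 ± 0.22), with a list median of -0.18 (adjusted p = 0.869). The glycolysis list had a median of -0.14 (adjusted p = 0.239; 0.0257 without ConA replicate 2), with 0 genes passing.

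Of 18 heat shock and dissociation stress genes, Hsp90aa1 rose over all genes. Adjusted over the list alone, 4 rose, Hsp90aa1, Dnajb1, Hspe1 and Dnaja1, and Egr1 fell; the list median was -0.11, its mean 0.092 and its test direction higher (adjusted p = 0.344; 0.00782 with the hepatocyte covariate). The unfolded protein and integrated stress list had a median of 0.21 (adjusted p = 0.336). Of 33 cell cycle genes, Pcna rose over all genes and adjusted over the list alone, with Mki67, a marker of cycling cells, at 906 ± 136 and 608 ± 184 CPM and a list median of -0.16 (adjusted p = 0.482; 0.0257 without ConA replicate 2). The apoptosis list had a median of 0.13, a mean of -0.11 and a test direction of higher (adjusted p = 0.73). Of 28 type I interferon response genes, Ifi27l2a rose over all genes and adjusted over the list alone, with a list median of 0.28 (adjusted p = 0.141; 0.0368 without ConA replicate 1). The interferon gamma response list had a median of 0.13 (adjusted p = 0.788) and the NF-kappaB and TNF list one of -0.055 (adjusted p = 0.5). In the unfolded protein, apoptosis, interferon gamma and NF-kappaB lists 0 genes passed over all genes or adjusted over the list alone.

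**Figure D2:**
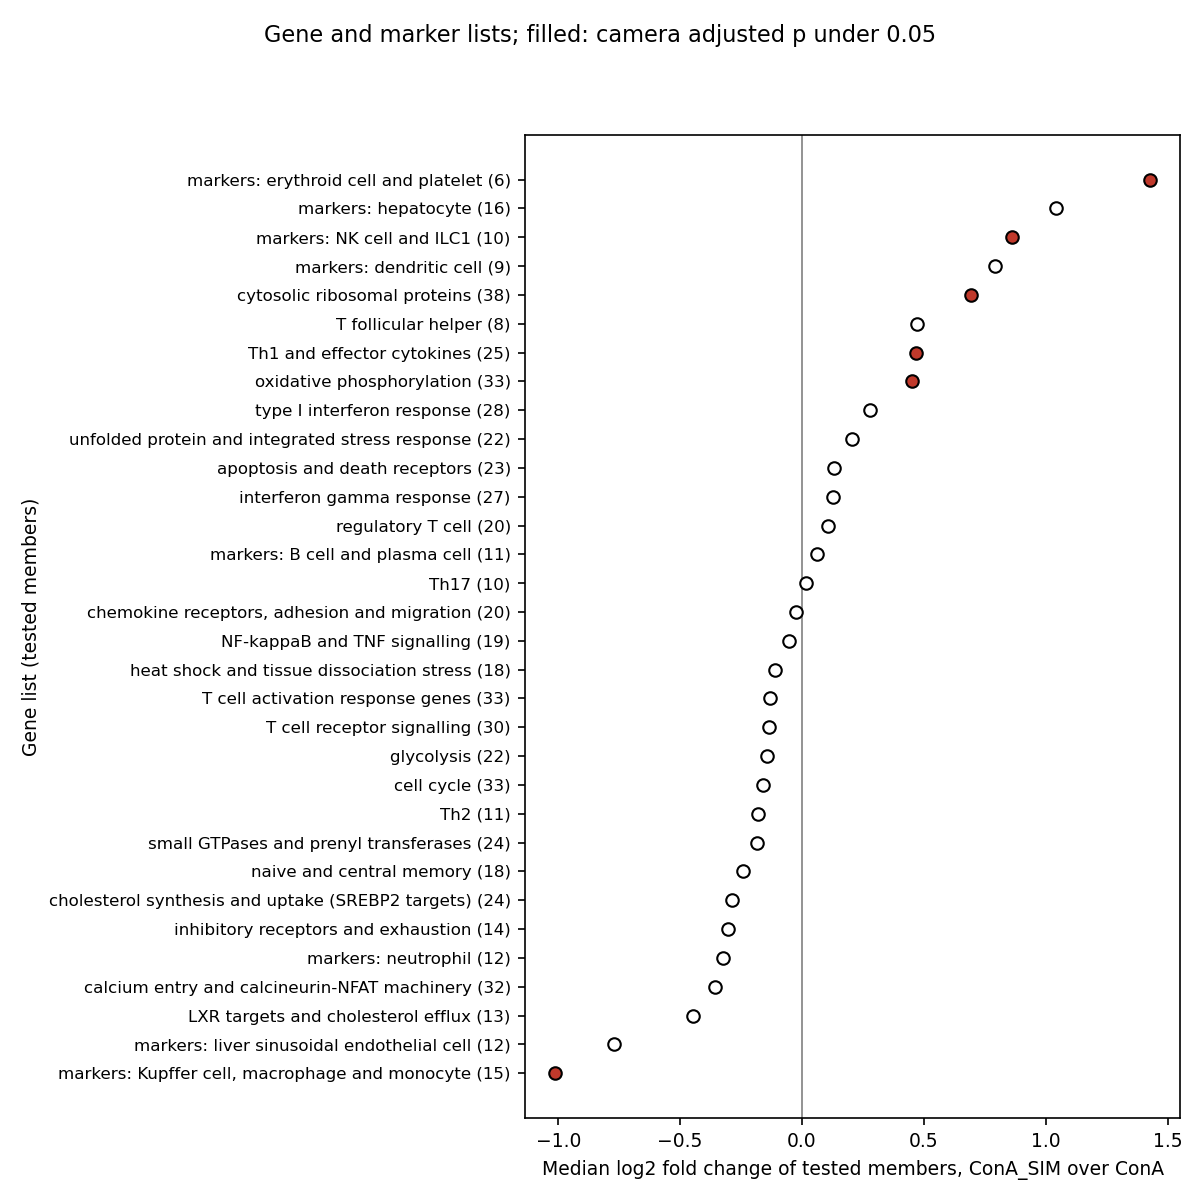
Median log2 fold change of ConA+SIM over ConA (horizontal axis) of the tested members of each of 32 gene and marker lists (vertical axis, tested members in parentheses); filled points mark a camera adjusted p under 0.05. Of the 6 filled lists 5 are higher, from 0.45 to 1.43, and 1 is lower, at -1.01; with an estimated correlation 0 of the 32 pass.

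Markers of other cell types differed between libraries as well as between groups. Erythroid and platelet markers were higher in ConA+SIM, with a median of 1.43 over 6 genes (adjusted p = 0.00429; adjusted p = 0.407 with an estimated correlation; 0.183 after transcript length correction, with a median of 0.92; 0.0654 with GC correction as well, with a median of 0.91; 0.12 without ConA replicate 3, with a median of 1.12). Hbb-bs rose over all genes and 2 genes, Hbb-bs and Hba-a2, adjusted over the list alone; near-identical globin genes can share reads. NK cell and ILC1 markers were higher, with a median of 0.86 over 10 genes (adjusted p = 0.00625; adjusted p = 0.407 with an estimated correlation; 0.187 after transcript length correction; 0.104 with the hepatocyte covariate). After length correction the median of this list was 0.87 and its mean 0.55 instead of 0.86, with a lower quartile of -0.38 instead of 0.25. With length and GC correction the median fell to 0.31 and the mean to 0.28 (adjusted p = 0.36). With the hepatocyte covariate the median was 0.70, but the mean was 0.090 and the lower quartile -0.60. Their summed level was 594 ± 74.0 CPM in ConA and 1112 ± 120 in ConA+SIM, 0 genes passed over all genes, and Klrd1, an NK cell receptor gene that activated T cells also express, rose adjusted over the list alone. Kupffer cell, macrophage and monocyte markers were lower, with a median of -1.01 over 15 genes (adjusted p = 0.0356; adjusted p = 0.822 with an estimated correlation), and 0 genes passed, also when adjusted over the list alone. That call ended without ConA replicate 1 (median -0.39, adjusted p = 0.442) or ConA+SIM replicate 2 (-0.56, adjusted p = 0.295) and with quality weights (-0.60, adjusted p = 0.372). It also ended with the hepatocyte covariate (adjusted p = 0.0724), where the difference was larger (median -1.50) and the median SE of its genes was 1.53 instead of 0.78. The summed level ran from 672 CPM in ConA+SIM replicate 2 to 3733 in ConA replicate 1.

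Hepatocyte markers had a median of 1.04 over 16 genes (adjusted p = 0.173), with Alb at 37.2 ± 31.2 and 64.4 ± 31.1 CPM. Sinusoidal endothelial markers had lower values in 12 of 12 genes and a median of -0.77 (camera adjusted p = 0.199, and 7.38e-04 without ConA replicate 1). Over 20 alternatives the median ran from -1.30 to 0.17. The summed level was 431, 2372 and 791 CPM in ConA replicates 1 to 3 and 460, 828 and 810 CPM in ConA+SIM replicates 1 to 3. In this sum only ConA replicate 2 lay above the ConA+SIM libraries. B cell and plasma cell markers had a median of 0.062 (adjusted p = 0.109) and a summed level from 138 CPM in ConA replicate 1 to 1526 in ConA replicate 2. That list was called higher without ConA replicate 2 (median 1.82, adjusted p = 4.35e-08), with limma-voom (1.36, adjusted p = 0.00788), with quality weights (2.02, adjusted p = 0.00271) and with the replicate block (1.29, adjusted p = 0.0221), but not with an estimated correlation (adjusted p = 0.822 with an estimated correlation). Dendritic cell markers had a median of 0.79 (adjusted p = 0.0881; 0.0257 without ConA replicate 2 and 0.0424 with the stricter filter), and Siglech and Clec9a rose adjusted over the list alone, the latter from 0 counts in all 3 ConA libraries. Neutrophil markers had a median of -0.32, a mean of -0.44 and a test direction of higher (adjusted p = 0.881), and the calprotectin genes S100a8 (1.41 ± 0.30) and S100a9 (1.20 ± 0.29) rose adjusted over the list alone. In the hepatocyte, endothelial and B cell lists 0 genes passed, also when adjusted over the list alone. Too few members were tested of the CD8 T cell (4), gamma delta and innate-like T cell (2), stellate cell (2), cholangiocyte (1) and sex chromosome (4) lists for a list test. In these lists 0 genes passed over all genes. Spp1, the sole cholangiocyte gene tested, was lower (-1.47 ± 0.64) at an edgeR p under 0.05 that is unadjusted, since a list of 1 gene leaves nothing to adjust for. It ran from 57.3 to 179 CPM in ConA and from 12.4 to 59.6 CPM in ConA+SIM, so the groups overlapped. Cd8a stood at 5.32 ± 9.15 CPM in ConA and 4.92 ± 5.14 in ConA+SIM.

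The libraries of the groups also differed in the lengths of the transcripts they held. Ribosomal protein genes took 9.36% ± 0.81 of counts in ConA and 15.5% ± 1.04 in ConA+SIM (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Transcripts of up to 1000 nt took 9.61% ± 0.44 and 15.0% ± 0.79, and transcripts over 4000 nt 31.5% ± 1.86 and 25.0% ± 1.05, with the same exact p. Of the 57 genes that rose, 50 had a transcript of up to 2000 nt, and their median was 946 nt against 3070 nt over tested genes. Among the 3400 genes above 64 CPM outside the ribosomal protein family, the log2 fold change correlated across genes with transcript length (Spearman rho -0.35) and with GC content (-0.37); genes are not independent replicates. With the length trend of each library removed, 0 of the 57 genes passed, and their median log2 fold change was 0.84 (median SE 0.25) instead of 1.24 (median SE 0.19). The trend was fitted on genes that included the 57 and the other ribosomal protein genes. A true rise of such mostly short genes would thus be removed in part, so the lost calls do not show length to be the cause. The SE was larger after correction in 55 of the 57. In 5 of them, Stk17b, Hsp90aa1, Sub1, Rps15a and Stk26, with transcripts taken as 3281 to 5179 nt long, the log2 fold change rose as well (Hsp90aa1 from 1.27 ± 0.15 to 1.41 ± 0.23), so their lost calls, all at an adjusted p of 0.249, did not come from a smaller fold. In Stk17b, Sub1 and Stk26 the log2 fold change grew by a larger share than the SE. A larger SE thus does not account for their lost calls either. The 5179 nt of Rps15a is the length of the 1 transcript taken for that gene, and its larger corrected value depends on that choice. With length and GC correction the log2 fold changes of these 5 ran from 0.43 to 1.57, that of Rps15a still above its uncorrected value. With that correction 0 of the 57 genes passed and their median was 0.79 (median SE 0.25).

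**Figure D3:**
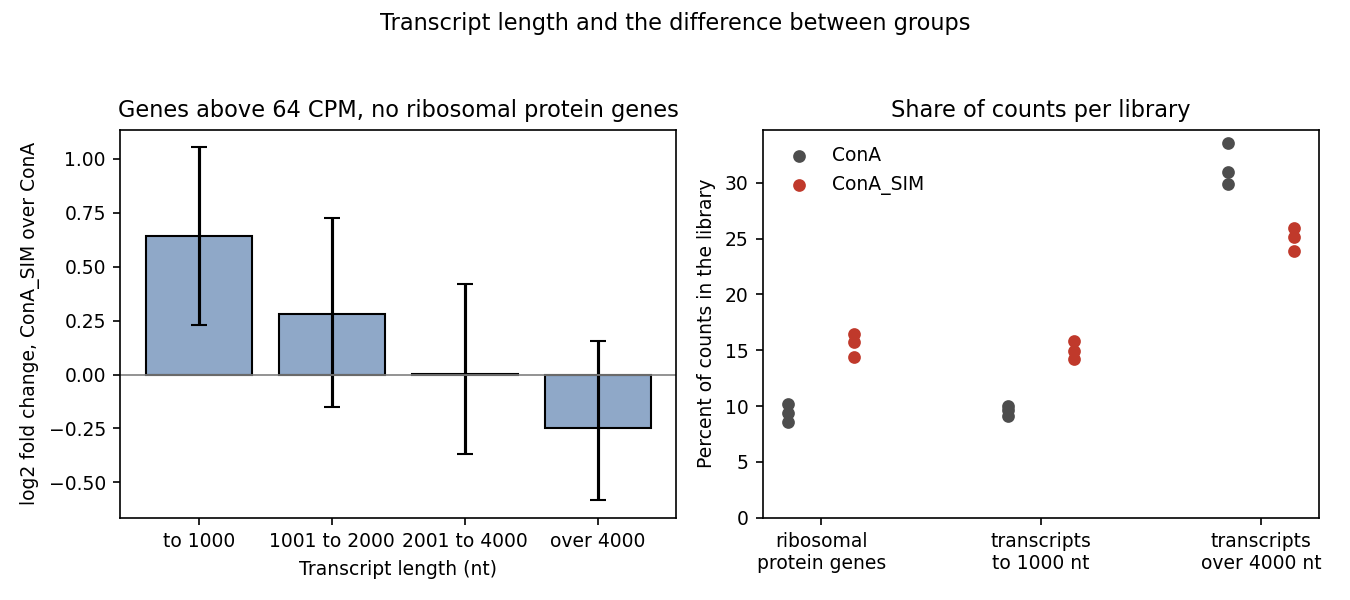
Left, median log2 fold change of ConA+SIM over ConA (bars; lines span the middle 50% of genes) by transcript length in nt, for genes above 64 CPM without ribosomal protein genes; the median runs from 0.64 for transcripts up to 1000 nt to -0.25 over 4000 nt. Right, percent of each library's counts (points, axis from 0) in ribosomal protein genes and in short and long transcripts; the ConA and ConA+SIM (ConA_SIM on the axis) libraries do not overlap in any of the 3 classes.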

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

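The length, GC, copy-row and ribosomal alternatives were chosen after the data were seen. The 57 edgeR calls kept their direction in every alternative that tested them. The count of changed genes was 540 with DESeq2, 115 with limma-voom and 114 with quality weights, and 0 with the hepatocyte covariate, with the length correction, with the length and GC correction and with ribosomal protein genes left out. In that last fit the log2 fold changes of Cd69 (1.34, adjusted p = 0.127) and Hbb-bs (2.07, adjusted p = 0.156) hardly moved. The adjustment is looser where many p-values are low, so the 19 calls outside the family depended on ribosomal protein genes being tested. Genes lower, 0 in the edgeR test, numbered 1 with RLE scaling, 1 without a low-count filter, 193 with DESeq2, 7 with limma-voom and 4 with quality weights. Without 1 replicate, the count ran from 0 to 3 and the count of changed lists from 5 to 10; such fits hold 5 libraries. The hepatocyte covariate shifted the median of all genes to -0.20. The 6 changed lists became 0 with an estimated correlation, 0 with fry and 2 (ribosomal proteins and Kupffer markers) with the length correction and with the length and GC correction. Where no construction explains a change, the cause was not tested. Replicate numbers did not pair the samples: same-numbered libraries had correlations of 0.011, 0.0088 and 0.033, and with the replicate block 0 genes were called. Among single named genes, 522 values under alternatives stayed on their side of the threshold, 190 lost it and 16 gained it; among lists 595, 26 and 16. Of 503 uncalled list values 43 changed direction. The simulated calls show that changes of 2-fold were below what this spread can detect.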

Other observations

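The tests of NK cell markers and of SREBP2 targets were chosen after the list results had been seen. The tests of length, GC content and ribosomal protein genes were set up once the length trend had been noticed, with their limits written before their own values were computed. The test against matched lists was run again with the same limit after a fault in its matching, missing coding lengths, had been found from the values of the earlier run and mended. Several further T cell genes had values that separated the groups without passing the edgeR test, where chance separates 10% of genes. Ly6c2, a marker of memory and effector T cells, stood at 231 ± 54.8 CPM in ConA and 460 ± 103 in ConA+SIM (n = 3 per group), the checkpoint gene Ctla4 at 276 ± 62.6 and 444 ± 87.0 CPM, and the stress factor Atf4 at 447 ± 53.5 and 674 ± 32.9 CPM. Ly6c2 belongs to the Th1 and effector list, called higher, and also to the Kupffer cell, macrophage and monocyte list, called lower. Its value is thus not one of T cells alone. On the lower side, the integrin genes Itgal and Itgb2, which form LFA-1, stood at 875 ± 49.5 against 588 ± 60.7 CPM and 812 ± 80.8 against 516 ± 70.2 CPM, and Maf, a factor of Th2 and follicular cells, at 225 ± 40.6 against 133 ± 23.7 CPM.

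In ConA+SIM replicate 2, 18.4% of tested genes had 0 counts, and the main axis of variation between libraries, with 37.0% of the variance, set this library apart from the rest. Genes at 0 in 1 library and at 50 CPM or more in another of the same group numbered 88 in ConA and 148 in ConA+SIM.

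The real grouping of the 6 libraries called 57 genes, and the highest of the other 9 splits into 3 and 3 called 0. For lists the real grouping called 6, 5 of the 10 splits called as many or more, and the highest other split called 7. With 10 splits no share under 0.05 can be reached, so the splits alone cannot settle whether either count is chance.

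Short transcripts and ribosomal protein genes were higher together in ConA+SIM, although the call of the ribosomal protein list was lost with an estimated correlation (adjusted p = 0.407 with an estimated correlation) and with fry (adjusted p = 0.0633). Within the ribosomal protein family, log2 fold changes were smaller at longer coding lengths over 82 genes (Spearman rho -0.41, permutation p = 0.00018). A uniform rise of the family laid over the length trend of other genes would give such a correlation too. The test therefore cannot argue against a uniform rise, and its permutation treats genes as independent. The ribosomal protein list's median of 0.69 lay narrowly past the limit for a length trend as the whole cause, at percentile 97.9 of 10000 lists. These lists held other genes matched on coding length and abundance. Their median was 0.33, and their central range, fixed beforehand as the limit, ended at 0.68. Matched genes were drawn singly, whereas those of the ribosomal protein list had an estimated correlation of 0.27, so that range may be too narrow. The test thus cannot decide whether length is the whole cause. Length correction lowered the list median from 0.69 to 0.28, which camera with its preset correlation still called (adjusted p = 1.9e-04). The trend removed was fitted on ribosomal protein genes as well, so part of a true rise may have been removed with it. GC content as the whole cause of the length trend is argued against by a partial correlation with length of -0.50 at fixed GC content. The partial correlation with GC content at fixed length was -0.51, so length does not account for the GC trend either. A group difference in RNA or library handling that depended on length or GC content may account for part or all of the rise. A simvastatin effect on ribosomal protein transcripts stays open as well, since the labels record no handling step apart from the group.

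The effector list was called higher in ConA+SIM with the preset correlation, but not with an estimated one (adjusted p = 0.407 with an estimated correlation) or after length correction (adjusted p = 0.2), and Gzma, 1 of the 10 tested NK genes, belongs to both lists. NK cells that escaped the gate, which excluded NK1.1-positive cells, are a candidate source of any such difference. The 5 tested markers that T cells do not usually share differed by 0.60 in mean log2 CPM, with an interval of 2 SE from -1.13 to 2.33, which neither excludes NK cells nor requires them. Of these markers Tyrobp was the most abundant, at 137 ± 40.4 CPM in ConA and 177 ± 133 in ConA+SIM. Myeloid cells also express Tyrobp, so the score does not measure NK cells alone. Effector T cells as the source stay equally open.

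Statins lower sterol synthesis, which would, as a hypothesis, raise SREBP2 targets in the cells it reaches. The mean log2 CPM of the list differed by -0.045 between groups, with an interval of 2 SE from -0.47 to 0.38, so neither a rise nor a fall may be read from it.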
